A study of Mus musculus with 6 samples.

How the data were processed

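Total RNA from the dissected basolateral amygdala of 6 male mice, 3 control and 3 under chronic restraint stress, was made into stranded, ribosomal RNA-depleted libraries and sequenced as single-end reads in a shared pool over several lanes, per the labels. The submitters' processing notes name FastQC 0.12.1, STAR 2.7.7a, HTSeq 0.13.5, edgeR 3.42.4 and the genome build mm39, without roles. The gene annotation and the strand setting of the counting are not given in the sources used here, so antisense and overlapping genes cannot be separated with certainty. The authors deposited raw counts per gene symbol, 1 file per library and 26264 symbols each, not normalized and not pooled. Symbols were used as the files give them and no coordinates are given, because the annotation at hand is of another build. In 15 sets holding 32 symbols with at least 60 counts over the libraries, the counts were identical in every library, so members of such sets, among them Hba-a1 and Hba-a2, were read as uncertain.

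Rows for reads assigned to no gene were kept out of library sizes and tests. Reads without a gene made up 53.0 to 57.4% of the reads in the files, reads aligned to more than 1 place 6.97 to 8.16% and ambiguous reads 0.162 to 0.194%; the row for low alignment quality equalled that for multiple alignment in every library and was counted once. Counts in genes were 35.5 to 38.6% of reads. Genes of near-identical copies lose reads in such counting, and the file held no mitochondrially encoded symbols under the names of the list for them, which was therefore not tested. Malat1 and Rn7sk each took over 1% of the counts in genes. No pair of libraries agreed within sampling noise: the lowest chi-square per gene was 2.95, between control 2 and stress 2.

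Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 14739 genes and removed 11525. TMM factors ranged from 0.983 to 1.02 and the biological coefficient of variation was 14.3%. The test was edgeR's quasi-likelihood F test with robust estimation and with the newer, non-legacy method, for stress minus control, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. SEs were computed as the absolute log2 fold change over the square root of F, and 95% intervals from the t distribution with the test's degrees of freedom. CPM values were computed here from the deposited counts and use TMM-scaled library sizes; list levels per library are means of log2 CPM with a prior count of 2.

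Before the data were examined, 38 gene lists were fixed, of which 37 had at least 3 tested genes; 26 list members were missing from the files. They were tested with camera at a preset correlation of 0.01, adjusted over lists, with an estimated correlation and with fry as alternatives. The named genes were chosen by a fixed rule. They are, per direction, 12 past the threshold with separate groups and a mean CPM of at least 1, filled to 6 by the smallest unadjusted p where fewer passed; for each list that passed, or that had a member past its own adjustment, the 3 members with the smallest p; for each other list 1 member; and 11 genes fixed in advance. For 1 list, 1 member that the rule takes is not reported here. The alternatives covered normalization, filtering, the replicate number as a block, other tests, each replicate left out and abundant genes left out. A further 5 were added after seeing the data: leaving out the 3 libraries with high Ttr, leaving out control 1 and stress 1, and 3 fits with the choroid plexus, striatal or oligodendrocyte level as a covariate. The fit without the 3 libraries with high Ttr kept control 3 as the only control, against stress 1 and stress 3. List tests with an estimated correlation within each of the other fits were also added after seeing the data. Gene results were recomputed under the settings that change the gene test and list results under those that change the list test; the correlations, the splits and the tests of single patterns were not recomputed.

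The procedure was tested on simulated counts with the means and library sizes of these 14739 genes, in 5 runs with 200 changed genes each. For stress against control it called 43.4% of 1.5-fold, 70.7% of 2-fold and 88.5% of 3-fold changes. Of 746 calls 76 were false (10.2%), above the nominal 5%. Of 50 sets of 20 genes shifted by 0.3 on the log2 scale 50 were called, and 2 of 150 unshifted sets; simulated genes were independent, so this does not cover lists whose genes vary together. The simulated spread is that of the model and leaves out differences in dissection.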

Results

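The series measured gene expression in the basolateral amygdala, the part of the amygdala that receives cortical and thalamic input and is central to fear and anxiety, in male mice. It compared 3 unstressed control mice with 3 mice kept under chronic restraint stress, in which an animal is held immobile repeatedly. Each mouse gave 1 library of total RNA after ribosomal RNA depletion, and the labels call the libraries of a group biological replicates. The title of the series concerns neuronal exosomes, the small vesicles that cells release from endosomes, together with the transcriptome. Controls 1 to 3 held 9916324, 10233706 and 9870139 counts in genes. Stress libraries 1 to 3 held 9919111, 9859449 and 10179081. Between 18559 and 18790 genes had at least 1 count per library. The share of reads that the counting assigned to no gene, which can include intronic and antisense reads, was 54.3 ± 1.13% in controls and 55.9 ± 1.27% under stress (two-sided exact permutation p = 0.2, where 0.1 is the smallest p that 3 against 3 allows).

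The main comparison asked which genes differ between stressed and control amygdala. Among genes with separate groups that were lower under stress, those with the smallest unadjusted p were Hpca, which encodes the neuronal calcium sensor hippocalcin, Irs4, an insulin receptor substrate, and Greb1, an oestrogen-responsive gene. Hpca was measured at 379 ± 18.0 CPM in controls and 277 ± 17.9 CPM under stress (SD, n = 3 each), a log2 fold change of -0.45 ± 0.07 (SE). Among those higher under stress the smallest unadjusted p was that of Ndst4, a heparan sulfate N-deacetylase/N-sulfotransferase, at 31.9 ± 5.49 CPM in controls and 53.0 ± 5.66 CPM under stress, a log2 fold change of 0.73 ± 0.14. No gene passed the threshold: 0 of 14739 tested genes had an adjusted p under 0.05 in edgeR's quasi-likelihood test, and the smallest adjusted p was 0.997. At an unadjusted p under 0.05 there were 496 genes, 300 lower and 196 higher under stress, where chance alone gives 737. The groups did not overlap in 1221 genes (8.28%), against 10% by chance for 3 against 3. Other tools called 4 genes (edgeR's likelihood ratio test, Hpca, Irs4, Greb1 and Ndst4), 2 genes (edgeR's exact test, Hpca and Irs4), 2 genes (DESeq2, Hpca and Ndst4) and 0 genes (limma-voom). Without control 3 the quasi-likelihood test called 1 gene, the ribosomal RNA gene Rn18s, which was lower under stress and was named after its value was seen.

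Of the remaining genes chosen by smallest unadjusted p, those lower under stress were led in size by Greb1 and Irs4. Greb1 was at 2.09 ± 0.700 CPM in controls and 0.470 ± 0.109 CPM under stress, with a log2 fold change of -2.12 ± 0.42 and a 95% interval from -3.09 to -1.16. Irs4 was at 5.14 ± 1.15 and 1.54 ± 0.650 CPM, with a log2 fold change of -1.73 ± 0.32 and an interval from -2.47 to -0.98. Both rest on few reads: Greb1 had 29, 16 and 18 counts in controls 1 to 3 and 4, 4 and 6 under stress, and Irs4 had 65, 45 and 45 against 8, 17 and 21. Inhba, a subunit of activin, stood at -0.82 ± 0.17, the amino acid transporter Slc6a20a at -0.93 ± 0.22 and the growth factor Fgf1 at -0.35 ± 0.07 on the log2 scale. Higher under stress were Apaf1, the core of the apoptosome, at 0.43 ± 0.09, Dcx, the microtubule-binding protein of migrating neurons, at 0.36 ± 0.08, the adhesion gene Dscaml1 at 0.34 ± 0.09, the transcription factor Lhx2 at 0.36 ± 0.09 and the non-coding RNA Mir9-3hg at 0.35 ± 0.09. None of these passed the threshold over all genes (adjusted p = 0.997 for each, edgeR). The groups did not overlap for any of these 12 genes, which is part of the rule that chose them.

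**Figure D1:**
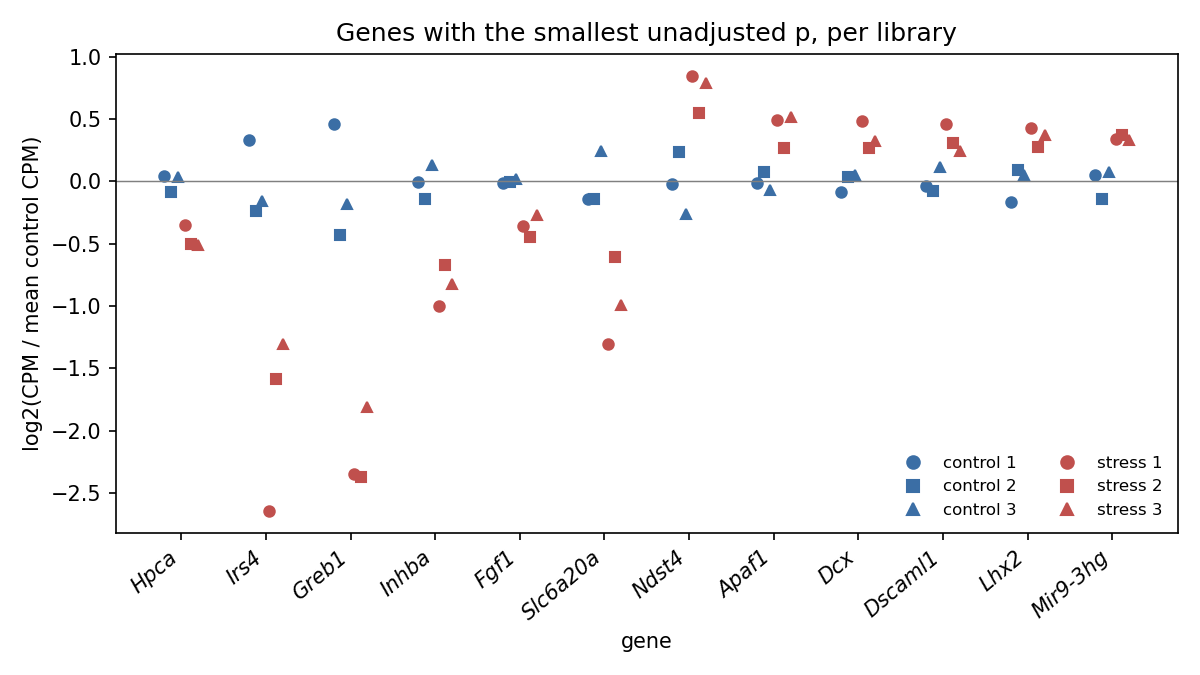
Each point is 1 library, drawn as the log2 of its CPM over the mean CPM of the 3 controls, for the 12 genes with the smallest unadjusted p among genes with separate groups (6 per direction). Blue marks control and red stress libraries; Greb1 and Irs4 show the lowest stress values, and the adjusted p was 0.997 for each gene shown.

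Genes fixed in advance for stress hormone action, exosomes and glutamate showed small differences. Fkbp5, a chaperone induced by glucocorticoids, had a log2 fold change of -0.07 ± 0.08 (SE, 95% interval -0.25 to 0.11), and the glucocorticoid receptor Nr3c1 one of 0.06 ± 0.07 (-0.11 to 0.23). The mineralocorticoid receptor Nr3c2 was at 0.07 ± 0.17, the corticotropin-releasing hormone receptor Crhr1 at 0.00 ± 0.20 (-0.46 to 0.47) and Bdnf at -0.05 ± 0.28 (-0.74 to 0.63). The exosome tetraspanin Cd63 was at -0.13 ± 0.33 (-0.91 to 0.64), and L1cam, a neuronal adhesion protein used to capture neuronal exosomes, at 0.08 ± 0.08 (-0.10 to 0.26). The insulin receptor gene Insr was at 0.06 ± 0.07 (-0.10 to 0.22), Irs1 at 0.03 ± 0.09, the cystine-glutamate exchanger Slc7a11 at -0.13 ± 0.09 and the metabotropic glutamate receptor Grm2 at 0.22 ± 0.27 (-0.44 to 0.88). Every one of these intervals includes 0. Crhr1 turned below 0 with library size alone (-0.01) and the direction of Crhr1, Nr3c1, Nr3c2, Bdnf, Cd63, Irs1 and Grm2 depended on single libraries.

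Among 18 tested receptors for serotonin, noradrenaline and dopamine, 3 passed when adjusted over the list alone, and 0 passed over all genes tested. The adjustment over the list alone was made for each of 37 lists, of which 2 had a member past it. It does not correct for the number of lists, so chance alone can give such lists. Htr4, a serotonin receptor coupled to cAMP, was at 19.5 ± 0.843 CPM in controls and 11.2 ± 2.96 CPM under stress (log2 fold change -0.80 ± 0.18, adjusted p = 0.0464 over the list alone, edgeR). The adrenergic receptor Adra2c was at 29.8 ± 5.53 and 19.8 ± 3.16 CPM (-0.58 ± 0.16, adjusted p = 0.0477). Htr1a, the inhibitory serotonin receptor, was higher under stress, at 17.1 ± 1.99 and 29.0 ± 8.34 CPM (0.76 ± 0.21, adjusted p = 0.0477). As a set the list was not called (camera adjusted p = 0.618). Among 21 apoptosis genes 1 passed over the list alone, Apaf1 (adjusted p = 0.0258), and the list was not called as a set (0.957). Its median of -0.04 and the test's direction differed in sign. Bcl2l1 was at 0.10 ± 0.06 and Casp8 at -0.38 ± 0.28. The receptor count was 0 without robust estimation, and 1 without a filter on low counts, with limma-voom or with the replicate block. It was 0 without control 1, control 2, control 3 or stress 1, and 2 without stress 2 or stress 3. The apoptosis count was 0 with the replicate block and without control 1, control 2, control 3, stress 1 or stress 3.

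Among the lists of markers for regions and cell types next to or within the basolateral amygdala, the striatal and central amygdala list had the largest median difference. Of 19 tested striatal and central amygdala markers, 19 were lower under stress, with a median log2 fold change of -0.99, and the set fell in camera (adjusted p = 3.62e-13). With an estimated correlation this call was lost (adjusted p = 0.636). Ido1 was at -1.52 ± 0.50, Isl1 at -1.70 ± 0.88 and Six3 at -1.25 ± 0.66. The mean log2 level of the list, relative to the control mean, was 0.60, -0.45 and -0.15 in controls 1 to 3 and -2.66, -0.50 and -0.43 in stress 1 to 3, and stress 1 was the lowest library for 19 of the 19 genes. Of 18 oligodendrocyte markers, 18 were lower (median -0.37, camera adjusted p = 1.88e-10; adjusted p = 0.636 with an estimated correlation, not called), among them the myelin genes Mobp at -0.52 ± 0.20, Fa2h at -0.48 ± 0.19 and Mal at -0.43 ± 0.19. The library values of this list were 0.41, -0.14 and -0.27 in controls and -0.58, -0.05 and -0.44 under stress. Astrocyte markers fell as a set with the preset correlation (15 of 17 lower, median -0.17, adjusted p = 0.00256) and were not called with an estimated one (adjusted p = 0.636), with Gja1, the gap junction protein connexin 43, at -0.25 ± 0.06 and Ntsr2 at -0.25 ± 0.09. With control 1 and stress 1 both left out, a fit chosen after seeing the data, the striatal median was -0.13 (adjusted p = 0.0201) and the oligodendrocyte median -0.02 (0.511). The striatal median was -0.49 without control 1 and -0.51 without stress 1, still called (3.15e-08 and 7.32e-08), and the oligodendrocyte median was -0.13 without control 1 (0.00143). The astrocyte median was -0.08 without control 1 (0.0482) and -0.05 without stress 3 (0.0432). In fits chosen after seeing the data, the astrocyte call ended with the oligodendrocyte level as a covariate (-0.08, 0.0833). The oligodendrocyte call ended with the striatal level as a covariate (-0.08, 0.140), and its median was -0.20 with the choroid plexus covariate (2.42e-05). Without the 3 libraries with high Ttr, control 3 was the only control, and the median was -0.03 for astrocyte and -0.20 for oligodendrocyte markers. The striatal median was -0.37 with the oligodendrocyte covariate (0.00218). The astrocyte median was -0.06 without control 1 and stress 1 (still called), -0.11 with the choroid plexus covariate (0.0265) and -0.09 with the striatal covariate (0.000715).

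Markers of vessels, meninges, blood and ventricle lining were also lower as sets with the preset correlation. With an estimated correlation none of these 5 calls held. Endothelial markers (15 of 17 lower, median -0.17, camera adjusted p = 0.000836; adjusted p = 0.636 with an estimated correlation) included Emcn at -0.39 ± 0.17, Slc2a1 at -0.23 ± 0.10 and Pecam1 at -0.28 ± 0.14. Pericyte and smooth muscle markers (9 of 10 lower, median -0.12, camera adjusted p = 0.0218; adjusted p = 0.636 with an estimated correlation) included Vtn at -0.18 ± 0.07, Acta2 at -0.43 ± 0.19 and Tagln at -0.54 ± 0.28. Meningeal fibroblast markers (11 of 12 lower, median -0.48, camera adjusted p = 0.000159; adjusted p = 0.636 with an estimated correlation) included the collagens Col3a1 at -1.80 ± 0.52 and Col1a1 at -1.03 ± 0.37, and Aebp1 at -0.72 ± 0.30. Red blood cell genes (6 of 6 lower, median -0.52, camera adjusted p = 0.000102; adjusted p = 0.636 with an estimated correlation) were led by Hbb-bt at -0.78 ± 0.32 and by Hba-a1 and Hba-a2, each at -0.57 ± 0.24. Hba-a1 and Hba-a2 hold identical counts in every library and cannot be read as 2 genes. With Hba-a2 left out the adjusted p was 0.000836. Choroid plexus and ependymal markers (14 of 14 lower, median -0.42, camera adjusted p = 0.00557; adjusted p = 0.737 with an estimated correlation) included Rarres2 at -0.75 ± 0.46, Foxj1 at -0.70 ± 0.85 and Ccdc153 at -0.56 ± 0.69. Their library values were 0.81, 1.56 and -2.38 in controls and -3.60, 1.72 and -3.21 under stress. Without control 3 the adjusted p was 0.280 for endothelial (median -0.09), 0.295 for pericyte (-0.05) and 0.0869 for meningeal fibroblast markers. Without stress 2 it was 0.0728 and 0.276 for the first 2 of these, and without control 1 it was 0.0551 for pericyte markers. The choroid plexus call ended without control 2 (0.296), stress 1 (0.384) or stress 3 (0.249), where the median turned above 0 (0.41, 0.12 and 0.07). Its median was -0.95 without control 3 (2.70e-05) and -4.30 without stress 2 (8.69e-16), and -1.13 with the replicate block (1.06e-09). The pericyte median was -0.21 without control 2 (0.00151), the meningeal median -0.25 without stress 1 (0.00339) and the red blood cell median -0.22 without control 3 (0.0292). The fits that follow were chosen after seeing the data. Without the 3 libraries with high Ttr, control 3 was the only control. The medians were then -0.95 for red blood cell, -1.21 for meningeal, -0.26 for pericyte, -0.33 for endothelial and -0.83 for choroid plexus markers. Control 3 was the highest of all libraries for red blood cell (0.40) and meningeal markers (0.36), so these medians describe that library. The choroid plexus call ended without control 1 and stress 1 (0.12, 0.735) and with the choroid plexus (-0.02, 0.649), striatal (0.31, 0.786) and oligodendrocyte (0.18, 0.993) covariates. The choroid plexus covariate is made of members of this list, so it removes the list's difference by construction. With the oligodendrocyte covariate the median was -0.79 for meningeal (1.42e-10) and -0.78 for red blood cell markers (1.88e-14), and with the choroid plexus covariate it was -0.27 for endothelial markers (2.53e-08).

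**Figure D2:**
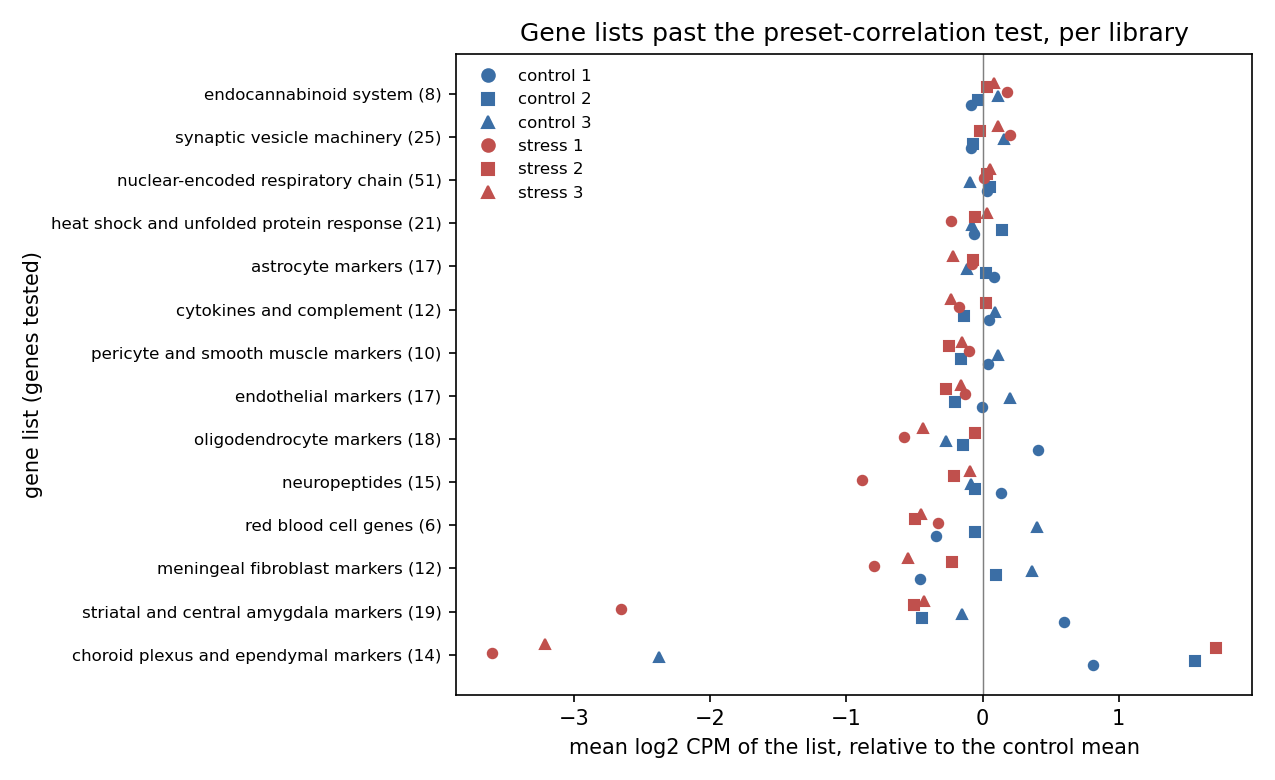
Each point is 1 library, drawn as the mean log2 CPM of a gene list relative to the mean of the 3 controls, for the 14 lists past camera with its preset correlation; the number of genes tested is in brackets. Blue marks control and red stress libraries; for the striatal list stress 1 lies at -2.66, and for the choroid plexus list control 3, stress 1 and stress 3 lie between -3.60 and -2.38.

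Other lists of function were also called with the preset correlation, and none of them with an estimated one. Neuropeptide genes fell as a set (12 of 15 lower, median -0.26, camera adjusted p = 0.00933; adjusted p = 0.636 with an estimated correlation). The tachykinins Tac2 and Tac1 were at -0.67 ± 0.23 and -0.79 ± 0.40, and Scg2 was at -0.46 ± 0.27. Stress 1 was the lowest library of this list too, at -0.89. Synaptic vesicle genes rose as a set (21 of 25 higher, median 0.12, camera adjusted p = 0.000145; adjusted p = 0.715 with an estimated correlation), with the active zone protein gene Rims1 at 0.28 ± 0.09, Sv2b at 0.25 ± 0.13 and Syt2, against the direction of the list, at -0.72 ± 0.42. Nuclear-encoded respiratory chain genes rose by a median of 0.04 (36 of 51 higher, camera adjusted p = 0.0271; adjusted p = 0.775 with an estimated correlation), with Ndufv1 at 0.14 ± 0.06, Sdhb at 0.12 ± 0.07 and Ndufs3 at 0.16 ± 0.10. Endocannabinoid genes rose by a median of 0.09 (7 of 8 higher, camera adjusted p = 0.0335; adjusted p = 0.636 with an estimated correlation). Abhd6 was at 0.20 ± 0.10, Faah at 0.20 ± 0.12 and Napepld at 0.15 ± 0.11, 3 genes for enzymes that degrade or make endocannabinoids and related lipids. Heat shock and unfolded protein response genes fell (17 of 21 lower, median -0.09, camera adjusted p = 0.0183; adjusted p = 0.737 with an estimated correlation), with the chaperones Hsp90b1 at -0.26 ± 0.10 and Hsph1 at -0.24 ± 0.10, and Creld2 at -0.37 ± 0.16. Cytokine and complement genes fell (10 of 12 lower, median -0.17, camera adjusted p = 0.0470; adjusted p = 0.636 with an estimated correlation), with Nfkb1 at -0.26 ± 0.10, Il1r1 at -0.47 ± 0.27 and C4b at -0.27 ± 0.18. The neuropeptide median was -0.47 without control 3 (0.00732), -0.17 without stress 1 (0.00397) and -0.67 without stress 3 (0.000344). The synaptic vesicle median was 0.05 without control 1 (0.0367), 0.23 without control 3 (1.88e-11), 0.06 without stress 1 (0.0239) and 0.20 without stress 2 (3.42e-06). Fits chosen after seeing the data ended 5 of these 6 calls, that of the respiratory chain excepted. For neuropeptides they were leaving out control 1 and stress 1 (-0.09, 0.0912) and the striatal covariate (-0.05, 0.646). For synaptic vesicles they were leaving out control 1 and stress 1 (0.0016, 0.833), and the choroid plexus (0.04, 0.125), striatal (0.03, 0.474) and oligodendrocyte (-0.01, 0.993) covariates. Without the 3 libraries with high Ttr, where control 3 was the only control, the synaptic vesicle median was -0.01. The endocannabinoid call ended in each of the 5 fits chosen after seeing the data (medians 0.03 to 0.07), of which 1 kept control 3 as the only control. The heat shock call ended without control 1 and stress 1 (-0.02, 0.178), and with the choroid plexus (-0.03, 0.137) and striatal (-0.00094, 0.576) covariates. Against control 3 alone, without the 3 libraries with high Ttr, the heat shock median was 0.03. The cytokine call ended without control 1 and stress 1 (-0.11, 0.251) and with the choroid plexus (-0.13, 0.0849), striatal (-0.09, 0.332) and oligodendrocyte (-0.11, 0.259) covariates. With the oligodendrocyte covariate the heat shock median was -0.06 (0.0163). The respiratory chain median was 0.07 without control 1 and stress 1 (0.000575) and 0.06 with the choroid plexus (0.00117) or oligodendrocyte (0.000312) covariate. Without the 3 libraries with high Ttr it was 0.14, against control 3 alone, the lowest library of this list (-0.09). Over the 6 libraries the synaptic vesicle level ran against the oligodendrocyte level (Pearson r = -0.844, exact permutation p = 0.0208, 0.0764 adjusted over 5 relations). The endocannabinoid call ended without control 1 (0.203), control 2 (0.116), stress 1 (0.265) or stress 3 (0.118), and its median was 0.14 without stress 2 (0.0327). The respiratory chain call ended without control 3 (0.925, with a median of -0.01), stress 2 (0.0728) or stress 3 (0.244), and with library size alone (0.0664, 0.02); its median was 0.08 without control 2 (0.000350). The heat shock call ended without control 2 (0.659, with a median of 0.01), stress 1 (0.505, -0.0037) or stress 2 (0.0975), and its median was -0.15 without control 3 (0.00370) and -0.16 without stress 3 (0.000829). The cytokine call ended without control 1 (0.0551, with a median of -0.11), control 3 (0.280, -0.09), stress 1 (0.153) or stress 3 (0.244, -0.11), with library size alone (0.0595) and with limma-voom in camera (0.0570).

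The lists closest to the theme of the series were not called in the main test. Of 38 tested exosome biogenesis genes, 24 were lower and 14 higher under stress, 0 had an unadjusted p under 0.05 and 0 passed over the list alone (camera adjusted p = 0.998). The median was -0.04 while the test's direction was up. Vps37b was at 0.20 ± 0.10. Of 30 insulin and IGF signalling genes, 12 were lower and 18 higher (median 0.01, adjusted p = 0.705), with Akt2 at -0.18 ± 0.09. Of 22 glucocorticoid-responsive genes, 17 were lower and 5 higher (median -0.09, adjusted p = 0.510), and Ddit4 was at 0.38 ± 0.15. Stress peptides and their receptors had a median of 0.06 over 11 genes (adjusted p = 0.893; mean -0.07), with Crh at -0.79 ± 0.41. Immediate early genes had a median of -0.02 over 21 genes against an upward direction in the test (adjusted p = 0.827), with Klf4 at -0.77 ± 0.25. With the preset correlation this list was called in both directions when libraries were left out: lower without control 1 (median -0.10, 0.0367), and higher without control 3 (0.18, 0.00632) or stress 1 (0.10, 0.00196). With an estimated correlation in the same fits it was not called (adjusted p = 0.809, 0.621 and 0.782). In a fit chosen after seeing the data it was called higher with the striatal covariate (0.04, 0.0486), but not with an estimated correlation (adjusted p = 0.882). Without the 3 libraries with high Ttr its median was -0.41, against control 3 alone, the highest library of this list (0.30). Glucocorticoid-responsive genes had a median of -0.15 without the 3 libraries with high Ttr, again against control 3 alone, their highest library (0.16).

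The other lists were not called in the main test, though some were under other settings. Glutamate receptors and transporters had a median of 0.05 (26 genes, camera adjusted p = 0.0627, Grik1 at 0.37 ± 0.14), GABA receptors and transporters one of 0.00 (17 genes, 0.893, Gabrg3 at -0.27 ± 0.10) and neurotrophin signalling one of 0.01 (11 genes, 0.387, Ntf3 at 0.83 ± 0.42). Glutamatergic neuron markers were higher in 12 of 13 genes (median 0.11, 0.0519, Slc17a7 at 0.25 ± 0.15) and GABAergic interneuron markers lower in 11 of 18 (median -0.13, 0.0532, Dlx5 at -0.53 ± 0.22). Cortical layer markers had a median of 0.13 (12 genes, 0.268, Plch1 at 0.40 ± 0.14), hippocampal markers one of 0.03 against a downward test (9 genes, 0.998, Prox1 at -0.31 ± 0.14) and thalamic and hypothalamic markers one of -0.34 (9 genes, 0.165, Rgs16 at -0.51 ± 0.19). Microglia markers had a median of -0.01 (19 genes, 0.420, Laptm5 at -0.38 ± 0.11) and oligodendrocyte precursor markers one of -0.07 (12 genes, 0.360, Sox10 at -0.22 ± 0.17). Axon guidance and adhesion genes had a median of 0.06 (40 genes, 0.360, Epha4 at -0.26 ± 0.07), extracellular matrix genes one of -0.04 (22 genes, 0.545, Mmp9 at 0.84 ± 0.38) and circadian clock genes one of -0.03 (16 genes, 0.467, Dbp at -0.41 ± 0.10). Histone acetylation genes had a median of 0.02 (24 genes, 0.165, Sirt3 at 0.23 ± 0.09), interferon-stimulated genes one of 0.04 (15 genes, 0.964, Gbp2 at -0.65 ± 0.27) and cytosolic ribosomal protein genes one of 0.00 (71 genes, 0.387, Rpl32 at 0.15 ± 0.07). None of the named members of these lists passed over all genes or over its list alone. Glutamate receptors were called higher without control 1 (median 0.06, 0.0411), control 3 (0.07, 0.0145), stress 2 (0.12, 0.00182) or stress 3 (0.07, 0.0432). With an estimated correlation in the same fits they were not called (adjusted p from 0.650 to 0.809). Glutamatergic markers were called higher without control 3 (0.29, 6.67e-06) or stress 2 (0.18, 0.0327), with library size alone (0.09, 0.0350) and with the replicate block (0.10, 0.0473), but not with an estimated correlation (adjusted p from 0.621 to 0.755). GABAergic markers were called lower without control 2 (-0.18, 0.00762), stress 1 (-0.17, 0.0425) or stress 3 (-0.06, 0.0305) and with RLE factors (-0.12, 0.0488), but not with an estimated correlation (adjusted p from 0.573 to 0.809). Circadian clock genes were called lower without control 2 (-0.08, 0.0145) and ribosomal protein genes higher without control 1 (0.05, 0.00925), but not with an estimated correlation (adjusted p = 0.523 and 0.809). In fits chosen after seeing the data, ribosomal protein genes were called higher without control 1 and stress 1 and with each covariate (adjusted p from 0.000305 to 0.0277). With an estimated correlation they were not called (adjusted p from 0.799 to 0.989). Without the 3 libraries with high Ttr, control 3 was the only control. The medians were then 0.11 for ribosomal protein genes, -0.15 for circadian clock genes and 0.67 for hippocampal markers. Without control 1 and stress 1, glutamatergic (-0.11, 0.0176) and hippocampal markers (-0.06, 0.0286) were called lower, but not with an estimated correlation (adjusted p = 0.946 for each).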

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

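The fits that leave out 2 or 3 libraries together and those with a marker level as a covariate were chosen after seeing the data. Over the settings fixed before the data were examined the count of genes past the threshold stayed at 0 except in 4 cases, whose cause was not tested beyond the tool: the likelihood ratio test gave 4 (1 higher, 3 lower), edgeR's exact test 2 (2 lower), DESeq2 2 (1 higher, 1 lower), and leaving out 1 replicate gave 0 to 1 (0 to 1 lower; 1 without control 3). Hpca had an adjusted p of 0.00259 in DESeq2, within a range of 0.00259 to 1.00 over all alternatives. Same-numbered controls and stress libraries were not consistently alike: they correlated at -0.32, 0.53 and 0.28, and control 1 was closest to stress 2. These correlations cannot show whether equal numbers shared a litter, cage or day, which the labels do not state. The replicate block gave 0 genes and 15 lists, 14 of them among the 14 reported, with 1 receptor and 0 apoptosis genes past the adjustment over the list alone; under the 5 settings added later these counts were 0 to 1 and 0.

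The 14 lists became 0 with an estimated correlation and 0 with fry (smallest adjusted p 0.636 and 0.621), 8 with the striatal level and 9 with the oligodendrocyte level as a covariate, of which 6 and 8 were among the 14. Leaving out 1 replicate gave 12 to 14 lists, and 6 lists held each time; of the 23 lists not called in the main test, 6 were called in at least 1 of these fits. With an estimated correlation, 0 lists were called in each of the 19 fits tried with it (smallest adjusted p 0.308), a combination added after seeing the data. Of 91 named genes, 84 kept their direction under every setting fixed beforehand and 78 under those added later too. Most of the 91 were chosen by a small p in these data, so these counts cannot show how stable directions are. The genes that turned under settings fixed beforehand were Crhr1, Bdnf, Cd63, Nr3c2, Irs1, Nr3c1 and Grm2. All of them belong to the genes fixed in advance, which were not chosen by their p. Directions that turned belonged mostly to genes with differences near 0. Crhr1 was at -0.014 with library size alone and at -0.0010 with the replicate block. With 1 replicate left out the ranges were -0.19 to 0.18 for Crhr1, -0.28 to 0.15 for Bdnf, -0.46 to 0.067 for Cd63, -0.13 to 0.18 for Nr3c2, -0.0071 to 0.11 for Irs1, -0.012 to 0.097 for Nr3c1, -0.13 to 0.41 for Grm2 and -0.010 to 0.075 for the respiratory chain list.

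Without the 3 libraries with high Ttr, control 3 was the only control, so these values rest on that library. Faah was then at -0.034, Fkbp5 at 0.023, Crhr1 at -0.16, Insr at -0.048, Cd63 at 0.19 and L1cam at -0.00096. Without control 1 and stress 1, Nr3c2 was at -0.14, Crhr1 at -0.23, Grm2 at -0.18, Irs1 at -0.038, Cd63 at 0.046 and L1cam at -0.015. With the choroid plexus covariate, Crhr1 was at -0.19, Grm2 at -0.033 and Cd63 at 0.15. With the striatal covariate, Nr3c1 was at -0.027, Nr3c2 at -0.22, Crhr1 at -0.25, Grm2 at -0.26, Bdnf at 0.11, Irs1 at -0.050, L1cam at -0.012 and the striatal list itself, which the covariate removes by construction, at -0.023. With the oligodendrocyte covariate, Sox10 was at 0.040, Ccdc153 at 0.023, Nr3c2 at -0.042, Crhr1 at -0.23, Grm2 at -0.11, Cd63 at 0.21, the synaptic vesicle list at -0.012 and the choroid plexus list at 0.18. The cause of these turns was not tested. Fewer libraries or an added term also leave fewer degrees of freedom. At 9859449 counts or more per library, depth limits genes such as Greb1, with 4 to 29 counts.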

Other observations

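The tests of the choroid plexus, striatal and oligodendrocyte patterns were chosen after the results were seen, and the splits were set before. For Irs4 and Greb1 the list and the rule were set before their test, but both genes had been chosen by their p in these data. The spread between libraries was brought into these tests, apart from the splits and the ratio to Ttr, after their values were seen, and it left open 4 explanations that the tests without it had argued against. Some transcripts outside the lists stood out in single libraries and were chosen after their values were seen. Control 3 held 988 counts of Gh and 123 of Prl, the pituitary hormones, against 8 to 99 and 2 to 12 in the other libraries. Rn18s had 1776 and 1606 counts in controls 1 and 2 and 204 to 312 in the other 4 libraries.

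Oligodendrocyte and synaptic vesicle levels ran against each other over the 6 libraries (Pearson r = -0.844, exact permutation p = 0.0208; Spearman rho = -0.886, p = 0.0333), and r was -0.740 without control 1 and stress 1. With glutamatergic markers r was -0.843 (permutation p = 0.0306; rho = -0.886, p = 0.0333) and -0.343 without those libraries, so that relation rests on them. Over the 5 relations computed the Benjamini-Hochberg adjusted p was 0.0764 for both. For oligodendrocyte against striatal levels r was 0.775 (permutation p = 0.106, adjusted 0.176; rho = 0.486, p = 0.356; -0.325 without those libraries), against the respiratory chain 0.175 (p = 0.672, adjusted 0.672; rho = 0.257, p = 0.658; 0.106), and for choroid plexus against meningeal levels 0.347 (p = 0.451, adjusted 0.564; rho = 0.600, p = 0.242; 0.0785 without stress 1 and stress 2).

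Choroid plexus genes were lower under stress on average, with 21408, 38953 and 185 counts of Ttr in controls and 28, 55132 and 84 under stress. Over 9 choroid plexus genes, Ttr among them, stress 2 exceeded the highest control by 0.33 on the log2 scale (SD 3.35 between libraries of a group). Over the 14 genes of the list it did so by 0.16 (SD 2.57). A fall was thus not seen in stress 2, the highest of all libraries. By the rule set for it, a fall shared by the stress libraries cannot be told apart from none. That rule used this SD, which holds the gap between high and low Ttr within each group, so it could hardly decide. The test of choroid plexus tissue in some dissections could not tell it apart from other causes, because it compared stress 2 with control 2, both high in Ttr. Over the 8 genes other than Ttr the log2 ratio of stress 2 to control 2 differed from that of Ttr by a median of 0.30. That of Ttr was itself only 0.56, so an unchanged gene would pass the bound of 1. Folr1 and Kcnj13 followed Ttr over the libraries. Folr1 had 180, 312 and 6 counts in controls and 1, 431 and 1 under stress. Kcnj13 had 365, 660 and 19 against 1, 775 and 5. These genes were high together in controls 1 and 2 and stress 2, so their level does not follow the stress label. Whether stress also alters the tissue's own transcripts stays open.

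Striatal and central amygdala markers were lower under stress and lowest in stress 1. Less neighbouring striatal tissue in stress 1 as the whole cause cannot be told apart from other causes: without that library the median was -0.51 and the call held (camera adjusted p = 7.32e-08), but the groups' levels differed by only -0.47 (SE 0.40 between libraries). A change shared by the stress libraries cannot be told apart from none: the highest stress library differed from the lowest control by 0.014 (SD 0.97 between libraries of a group). With control 1 and stress 1 both left out the median was -0.13. Uneven amounts of neighbouring tissue over all 6 dissections, control 1 included, could give the rest, and no test here separates that from an effect of stress.

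Oligodendrocyte markers were lower under stress, and control 1 was the highest library. More white matter in control 1 cannot be told apart from other causes: without it the median shrank to -0.13, under 50% of its size, but the list was still called (adjusted p = 0.00143). With stress 1 left out as well it was -0.02 and not called (0.511). A fall in every stress library cannot be told apart from none: stress 2 exceeded the lowest control by 0.22, within an SD of 0.32 between libraries of a group. An effect of stress in some animals stays open and untested.

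A hypothesis for Irs4 and Greb1, both low-count genes, was that the stress dissections held less medial amygdala or hypothalamic tissue, where they may be expressed. A list of 20 other markers of these regions, written before its test, had 15 tested genes, 12 of them lower, with a median of -0.49 (SE 0.10 over genes); its levels were 0.21, 0.23 and -0.44 in controls 1 to 3 and -1.06, -0.07 and -0.45 in stress 1 to 3. Its members Tac1 and Lhx9 were also in lists fixed in advance. Its member Prlr was at 64.2, 115 and 4.29 CPM in controls 1 to 3 and 4.83, 119 and 6.75 CPM in stress 1 to 3. Prlr was thus high in the libraries with high Ttr, so the list levels and their spread partly follow those libraries. The median is above the bound of -0.86, set from the smaller of both differences. The bound took its spread over genes, which was wrong because the markers vary together: between libraries the list's group difference was -0.53 with an SE of 0.36, so -0.86 lies within it. Such tissue therefore cannot be told apart from other causes; the camera p was 3.49e-06 with the preset correlation and 0.0509 with an estimated one.

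The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. For genes past the threshold the real split gave 0 and the highest other split 322; with 0 in the real split, that 10 of the 10 splits gave as many was fixed beforehand and says nothing. For genes at an unadjusted p under 0.05 the values were 496 and 2157, with 5 splits as large. For gene lists they were 14 and 13, with 1 split as large, the real one. Every other split called at least 8 lists with the preset correlation, so splits that mix the groups also call many lists. The split that called 322 genes sets controls 1 and 2 and stress 2, the libraries with high Ttr, against the others, and points to a structure of the samples. The first principal component (54.9% of the variance) parts the same libraries.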
